A study of Mus musculus with 12 samples.

How the data were processed

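Mature mouse oocytes, knockout or wild type for Dicer by the labels' titles, were profiled on 12 arrays, 6 per group. Per the labels' protocols, total RNA was extracted with Trizol and turned into digoxigenin-labelled cRNA by a NanoAmp kit that couples reverse transcription to in vitro transcription. Per the labels' descriptions the material was a single cell, while the number of oocytes per array and the females are not given in the sources used here; each array was treated as a separate sample. Replicate numbers follow sample order only, so no arrays were paired. Per the file headers all 12 arrays share 1 scan date, so no scan batch could be tested. The array numbers in the titles run through the knockout arrays first, so an effect of array order cannot be told apart from genotype.

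Per the file headers the arrays were Mouse Genome Survey Microarrays, version 1.0, read with the AB1700 Expression Array System image software, version 1.1.1. The deposited scanner files hold for each spot a signal on a linear intensity scale, its error, a normalized intensity, a signal-over-noise score and other values such as quality flags, which are bit sums, per the file headers. Checked on the values, the signal equals its error where signal over noise is below 1, so dim probes sit on a noise floor, and the software's normalized intensity is the signal divided by 1 of 2 factors per array, set for separate parts of the array. The largest ratio of the factors within an array was 1.68. The authors' deposited series table also holds linear intensities, and its making is not given in the sources used here. Of its values, 93.8% lay within 1% of a quantile normalization of the signals done separately within each group, and 0.0205% within 1% of that over all 12 arrays. Its columns had medians of 257 to 260.4 in the knockout group and 215 to 217 in the wild-type group, and its missing cells were the spots with a bad-spot flag. Such scaling keeps any brightness difference between the groups, so that table served as an alternative only.

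Spots with a flag of 5000 or more were set to missing, control spots were left out, and the signals of 33012 probes were quantile-normalized over the 12 arrays and log2-transformed with no offset. Quantile normalization gives each array the same distribution, so fold changes are relative to the rest of the array. A probe was above background where its signal-over-noise score was at least 3, and was tested if that held on at least 6 of 12 arrays, counted without regard to group; 6088 probes were tested. Knockout was compared with wild type in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and a log2 fold change of 1 as the size threshold. Every adjusted p of a probe comes from limma. Single array measures were compared by exact two-sided permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

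The fit was tested on simulated data with the means and spreads of the 6088 tested probes and 200 changed probes. It recovered 62% of 100 probes changed 4-fold and 17% of 100 changed 2-fold, and 2.47% of its 81 calls were false. The simulation started from normalized values without a brightness difference, so this share does not cover false calls that arise from scaling. A first pass mark on the recovery at 4-fold was missed and was replaced, after the result was seen, by marks on bias and false calls; the estimates at 4-fold were off by -0.04 on the log2 scale. With few changed probes, changes of 4-fold or less are thus often missed at 6 arrays per group. In the real data 50.5% of the tested probes were called, so these shares may not hold for this comparison.

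The files pair probes with Celera gene identifiers (27930 probes), with AK, RefSeq or BC accessions (4181, 517 and 337) or with others (47). Names came from a RefSeq gene table of assembly GRCm38.p6 without versions: 311 probes matched by accession and 6 by synonym, giving 311 distinct symbols and 0.960% of probes. For a gene with several probes the one with the highest mean signal was kept, and a tested Prr18 probe was at -0.31 where the other probes of that gene were at 2.18 and 1.92. The genes named were fixed before the data were examined: Dicer1, then the 10 largest rises and 10 largest falls among named probes with an adjusted p under 0.05 and no overlap between groups, then up to 4 past the threshold from each of 23 gene lists, or its 1 or 2 brightest tested members. Obox2, dimmer than the other tested Obox genes and not past the threshold, was named beyond this rule. Set tests needed 4 tested members and no list had them. Sites of microRNA seeds were not analysed here, since they need 3' UTR sequences. No coordinates are given, since the files name no genome build.

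Alternatives fixed before the data were examined were centring on the median, cyclic loess, the scanner software's normalized signal or the deposited table (both were run), a normexp background with an offset of 50, an offset of the median noise, other filters on dim probes, a trended robust variance, array weights and leaving out each array. Alternatives chosen after seeing the data were quantile normalization over the tested probes or within parts of the array, lower bounds under 5 other scalings, the brightness of other sets of probes, scaling to each kind of control spot, fold changes relative to their median, and leaving out the pair of arrays with the closest numbers of detected probes.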

Results

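Transcript levels of mature mouse oocytes lacking Dicer, the RNase III enzyme that cuts the precursors of microRNAs and small interfering RNAs, were measured beside those of wild-type mature oocytes. The labels gave 12 arrays, 6 from Dicer-knockout oocytes and 6 from wild-type oocytes. Each was a 1-colour chemiluminescent array with 33012 gene probes, hybridized with digoxigenin-labelled cRNA that had been amplified from total RNA. The labels gave neither the number of oocytes behind an array nor the females they came from, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision of every value.

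More probes were above background on knockout arrays than on wild-type arrays. On average 8456 ± 759 probes were above background on the knockout arrays and 6255 ± 560 on the wild-type arrays (SD, n = 6 each; exact two-sided permutation test, p = 0.00216, the smallest that 6 against 6 arrays can give, and 0.00379 after Benjamini-Hochberg adjustment over 7 array measures). The knockout arrays ranged from 7361 to 9598 probes and the wild-type arrays from 5707 to 7102. The median signal of the 6088 tested probes was 4482 ± 1531 intensity units on the knockout arrays and 1501 ± 563 on the wild-type arrays (SD, n = 6 each), a 2.99-fold difference by geometric means (exact two-sided permutation test, p = 0.00216, adjusted 0.00379). The tested probes had to be detected on 6 of 12 arrays, which knockout arrays alone could meet. Over the 2979 probes above background on all 12 arrays the difference was 2.74-fold (exact permutation p = 0.00433). Over all 33012 probes, most of them at the noise floor, it was 1.20-fold (exact permutation p = 0.0844, adjusted 0.118). The control spots showed no such difference. Hybridization controls were 1.05-fold as bright on the knockout arrays (exact permutation p = 0.606, adjusted 0.606) and in vitro transcription controls 0.835-fold as bright (exact permutation p = 0.335, adjusted 0.391).

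**Figure D1:**
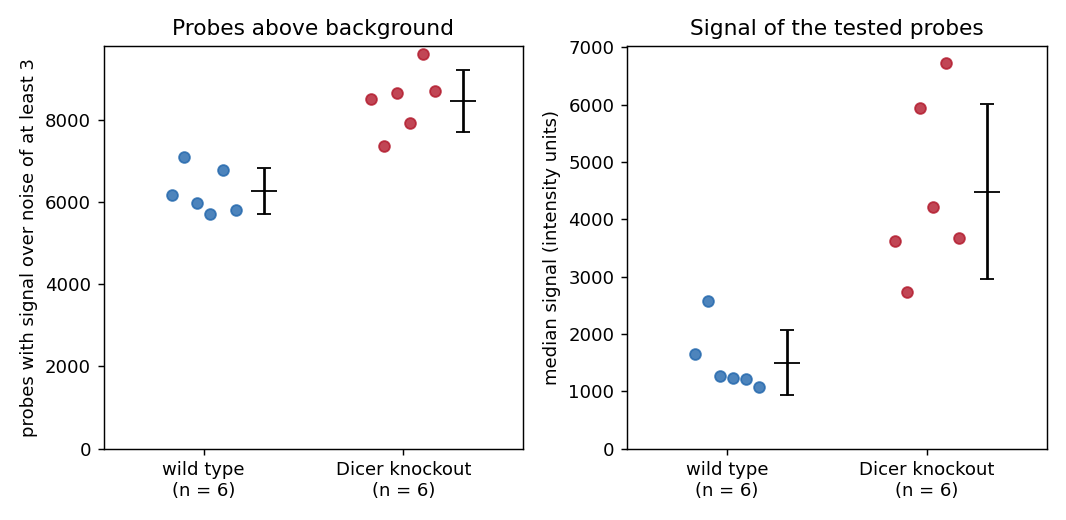
Left, the number of probes with signal over noise of at least 3 on each array; right, the median signal of the 6088 tested probes on each array, in intensity units. Points are arrays (6 wild type, 6 Dicer knockout) and bars give the mean ± SD; each knockout array lies above each wild-type array, from 7361 probes up against 7102 or fewer, and from a median of 2736 up against 2580 or less.

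The comparison of knockout with wild-type oocytes asked which maternal transcripts differ when Dicer is missing. Dicer1 itself could not be checked, because none of the 317 probes that could be paired with a gene symbol was named Dicer1. Among named genes, Mos, the kinase that starts the MAP kinase cascade of meiosis and keeps eggs in metaphase II, was 10.3-fold higher in knockout oocytes, at a log2 signal of 13.69 ± 0.52 against 10.33 ± 1.15, with 5 of 6 wild-type arrays above background (SD, n = 6 each; log2 fold change 3.36 ± 0.48 SE, adjusted p = 0.000102). Fgf21, a secreted hormone of fasting metabolism, was above background on 6 of 6 knockout arrays and not well above background on any wild-type array, which put it at least 25.2-fold higher after quantile normalization and at least 13.9-fold higher under the scaling with the lowest bound (log2 signals 12.17 ± 0.89 and 7.51 ± 0.65, adjusted p = 2.99e-06). Sf3b5, a subunit of the SF3b splicing complex, rose 3.20-fold (log2 fold change 1.68 ± 0.24 SE), and Cphx1, a homeobox gene of oocytes, rose 1.97-fold (0.98 ± 0.22 SE). Relative to the rest of each array, Eola1 and Coa3, an assembly factor of cytochrome c oxidase, were lower in knockout oocytes, with log2 fold changes of -2.18 ± 0.21 and -2.26 ± 0.29 (SE; adjusted p = 4.94e-06 and 4.35e-05).

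Among named genes whose groups did not overlap, the other large rises were those of C130026I21Rik (log2 fold change 5.86 ± 0.56 SE), Vmn1r148, a receptor of the vomeronasal family (3.91 ± 0.56), Krtap9-3, a keratin-associated protein gene (3.04 ± 0.43), and Ghdc (1.94 ± 0.36). These were above background on 2, 1, 1 and 2 of the 6 wild-type arrays in the same order, so the sizes of their rises rest on wild-type values partly at the noise floor. Pdxp, the pyridoxal phosphatase, and Unkl were not well above background on any wild-type array and were at least 9.03-fold and at least 5.01-fold higher in knockout oocytes after quantile normalization. Under the scaling with the lowest bound they were at least 4.91-fold and 2.48-fold higher. The bounds set the knockout mean against the lowest signal well above background, or the wild-type probe's own where higher. C130026I21Rik, Vmn1r148 and Krtap9-3 have near-identical copies in the mouse genome, so their probes may read more than their namesake. Under the same limit to groups without overlap, the other large falls were those of Rtl8c, a gene derived from a retrotransposon (-2.33 ± 0.39), Ramp3, an accessory protein of calcitonin-family receptors (-2.17 ± 0.32), and Gprasp1, a sorting protein of G protein-coupled receptors (-1.99 ± 0.36). They were followed by the ubiquitin ligase Wwp1 (-1.76 ± 0.34), the kinase Wnk4 (-1.54 ± 0.24), Mapk1ip1 (-1.54 ± 0.24), the steroid dehydrogenase family member Hsd3b4 (-1.45 ± 0.32), which also has near-identical copies, and the nucleolar GTPase Gnl2 (-1.38 ± 0.21). For these 20 genes all 6 knockout arrays lay on the same side of all 6 wild-type arrays, which the rule for naming them required. Of the 68 named genes tested, 17 were higher, 17 were lower and 34 did not pass an adjusted p of 0.05 in limma.

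Which of these 20 calls held depended on the scaling, and control spots or the authors' deposited table move nearly all probes upward in the knockout, which favours rises over falls by construction. Scaled to the hybridization control spots, 10 of the 10 largest rises and 1 of the 10 largest falls, Eola1, kept their direction and an adjusted p under 0.05. Scaled to the in vitro transcription control spots, 10 rises and 0 falls did, and Wwp1, Wnk4, Mapk1ip1, Hsd3b4 and Gnl2 had log2 fold changes above 0. The authors' deposited table kept 10 rises and 2 falls, Coa3 and Eola1. The scanner software's normalized signal kept 10 rises and 7 falls, without Mapk1ip1 (adjusted p = 0.115), Hsd3b4 (0.133) and Gnl2 (0.129). Centring each array on the median of its tested probes kept 10 falls and 9 rises, with Cphx1 at 0.61 (adjusted p = 0.0684). It moved the median log2 fold change of the tested probes from 0.18 to -0.19, which favours falls over rises by construction. The sizes moved too. Over quantile normalization (all or tested probes), median centring, cyclic loess, the scanner software's signal, both kinds of control spot and the authors' deposited table, the log2 fold change ranged from 3.17 to 5.04 for Mos, 1.61 to 3.45 for Sf3b5, 0.61 to 2.45 for Cphx1 and 5.27 to 7.13 for C130026I21Rik. It ranged from 3.27 to 5.18 for Vmn1r148, 2.26 to 4.10 for Krtap9-3 and 1.44 to 3.36 for Ghdc, and Eola1 and Coa3 stood at -0.41 and -0.46 when scaled to in vitro transcription controls. After quantile normalization the median log2 fold change was 0.76 in the dimmest eighth of the tested probes and -0.25 in the brightest. It was -0.12 and -0.50 with median centring and 0.03 and -0.03 with cyclic loess. Among probes above background on all 12 arrays it was -0.54 and -0.25 after quantile normalization. A rise from below background cannot enter there, so these values do not tell whether quantile normalization lifts dim probes.

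**Figure D2:**
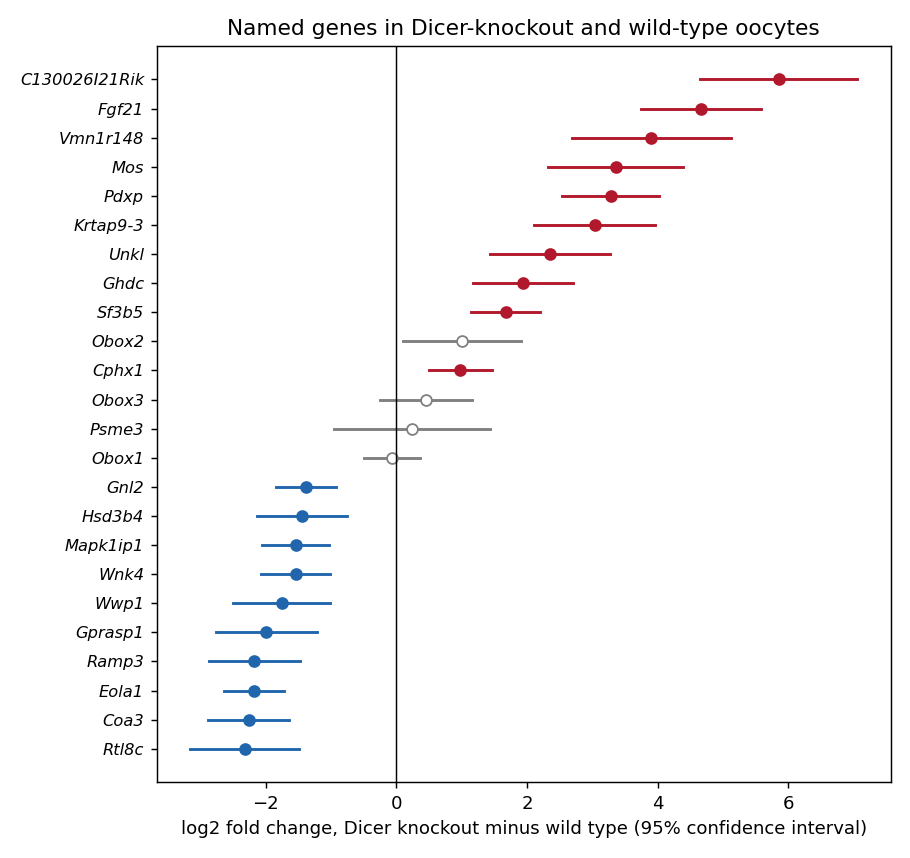
Log2 fold change (knockout minus wild type, quantile-normalized signal) of the named genes, with 95% confidence intervals from limma, 6 arrays per group. Red and blue points passed an adjusted p of 0.05 and open grey points did not; the values run from 5.86 for C130026I21Rik to -2.33 for Rtl8c, and the falls are relative to the rest of the array, since 1 of 10 held when arrays were scaled to hybridization controls.

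The gene lists fixed beforehand were mostly out of reach. Of 23 lists with 802 symbols, 8 had a member among the named probes and 3 had a tested member, so 0 lists had the 4 tested members a set test needed. In the list of meiotic cell cycle control, the single tested member, Mos, was higher (limma, adjusted p = 0.000102 over all probes). Its unadjusted p was 8.96e-06 in limma, with no other member of the list to adjust over. In the list of oocyte-specific genes, 3 homeobox genes of the Obox family were tested and 0 passed after quantile normalization, both over all probes and adjusted over the list alone. Each passed under some alternatives. Obox2 stood at a log2 fold change of 1.004 ± 0.42 (SE, adjusted p = 0.0605) and Obox3 at 0.46 ± 0.33 (adjusted p = 0.260). Without knockout replicate 2 both passed, at 1.32 (adjusted p = 0.00582) and 0.72 (adjusted p = 0.0268). Obox2 passed in 10 of 28 alternatives, among them cyclic loess at 1.06 (adjusted p = 0.0395) and hybridization controls at 2.47 (0.00162). Obox3 passed in 5 of 28, among them hybridization controls at 1.61 (0.00537). Both were above 0 in every alternative, between 0.77 and 2.83 for Obox2 and between 0.13 and 1.97 for Obox3. Obox1 stood at -0.07 ± 0.20 (adjusted p = 0.794), but its probe ranked between 2 and 17 in brightness on every array, where quantile normalization leaves it little room to move. Its estimate was -1.13 (adjusted p = 0.000537) with arrays centred on their medians and 0.49 (adjusted p = 0.0297) in the authors' deposited table. The Obox genes resemble each other closely, so their probes may read more than their namesake. In the list of proteasome and ubiquitin genes, the proteasome activator Psme3 stood at 0.25 ± 0.55 (adjusted p = 0.736), at -0.26 without wild-type replicate 6, and between -0.27 with cyclic loess and 1.603 (adjusted p = 0.0340) when scaled to in vitro transcription controls.

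The early-embryo genes Zfp352 and Tdpoz1, the translation repressor Eif4ebp1 and the transcription factor Jun were not well above background on enough arrays to be tested. Of the markers of other ovarian cells, the named ones were Sfrp4, above background on 1 of 6 knockout and 0 of 6 wild-type arrays, and the haemoglobin gene Hba-a1, above background on 1 of 6 arrays in each group. The lists with 0 named members held small RNA machinery, spindle and kinetochore, maternal-effect, pluripotency, RNA decay and storage, ribosomal protein, oxidative phosphorylation, glycolysis, p53 response, chromatin modifier, interferon response and piRNA genes, published targets of let-7 and of the miR-17 and miR-20 family, and sources of endogenous small interfering RNAs.

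Over all probes, 3077 of 6088 tested probes (50.5%) differed between knockout and wild-type oocytes at an adjusted p under 0.05 (limma, two-sided, Benjamini-Hochberg), 1711 of them higher in the knockout and 1366 lower. By size, 1508 were at least 2-fold higher and 1043 at least 2-fold lower, 124 were at least 16-fold higher and 10 at least 16-fold lower. The groups did not overlap for 1723 tested probes (28.3%), against 0.216% by chance. Of all probes, 178 were above background on each knockout array and on no wild-type array, and 3 the other way round. Some probes that rose more than any named gene, or fell more than any named gene, carried gene identifiers that the tables used here do not pair with names. The probe of mCG13815.1 was at least 253-fold higher in knockout oocytes, or at least 162-fold under the scaling with the lowest bound (log2 signals 16.33 ± 0.37 and 8.35 ± 0.75, SD, n = 6 each; adjusted p = 9.16e-09), and a probe of mCG14666.2 was at least 80.1-fold higher, or at least 44.8-fold, each with 0 of 6 wild-type arrays above background. Another probe of mCG14666.2 stood at 17.38 ± 0.72 against 9.16 ± 2.09, with 2 of 6 wild-type arrays above background. The probe of mCG21722.1 was lower in the knockout, at 9.45 ± 1.90 against 15.68 ± 0.58 with 3 of 6 knockout arrays above background. That of mCG147732 was lower too, at 8.53 ± 1.24 against 13.84 ± 0.34 with 2 of 6 (log2 signals, SD, n = 6 each).

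The split into higher and lower probes depended on the scaling. Against 1711 higher and 1366 lower, centring on the median of the tested probes gave 1393 and 1796, quantile normalization over the tested probes alone 1431 and 1750, the scanner software's normalized signal 2080 and 511, hybridization controls 3460 and 146, and in vitro transcription controls 4038 and 64. The authors' deposited table gave 3842 and 146. The median log2 fold change of the tested probes was 0.18, -0.19, -0.15, 0.55, 1.29, 1.65 and 1.39 in the same order. Taken relative to the median of 0.18, 1468 probes were higher and 1614 lower.

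**Figure D3:**
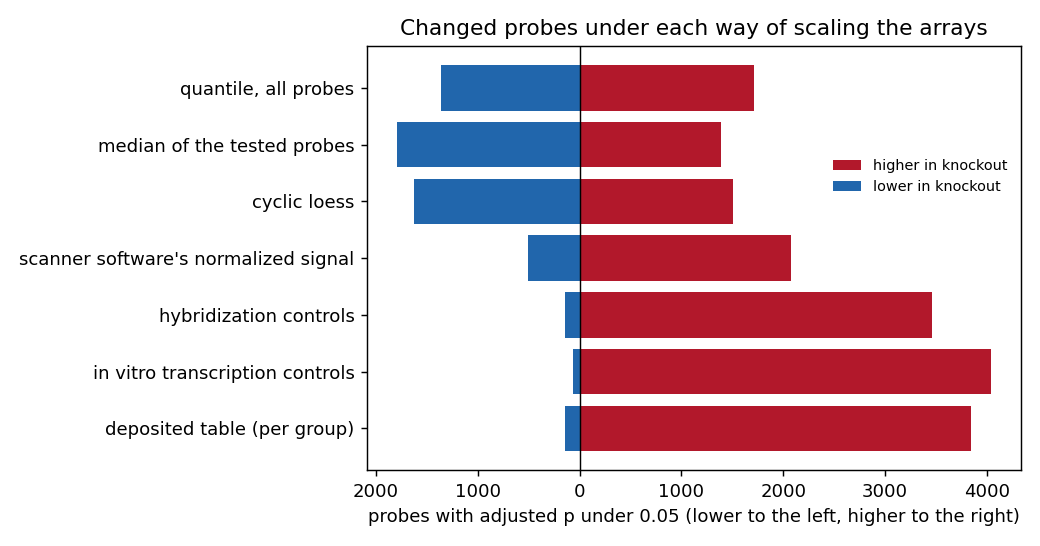
Number of probes with an adjusted p under 0.05, lower in the knockout to the left and higher to the right, out of 6088 tested probes, for each way of scaling the 12 arrays. The lower probes number 1366 after quantile normalization, 146 after scaling to hybridization controls and 64 after scaling to in vitro transcription controls.

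The arrays separated by group. Genotype, array order and brightness all divide the arrays in this way, so the separation cannot be credited to genotype alone. Over the tested probes, the correlation of log2 signal averaged 0.923 between knockout arrays (0.870 to 0.944), 0.897 between wild-type arrays (0.889 to 0.914) and 0.771 between arrays of different genotype (0.708 to 0.832), across genes, which are not independent replicates. The first principal component held 52.4% of the variance, with the knockout arrays between -75.7 and -50.3 and the wild-type arrays between 43.2 and 70.98.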

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

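The search for outlying arrays and the test of other groupings were fixed before the results were seen, as was the test on the left-out replicates 2; the tests on control spots, on probes detected in knockout oocytes alone in all left-out pairs, on rank correlations, on named markers, and on those replicates taken separately for higher and lower probes were chosen only after the result was seen.

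In 9 of 68 groups of 6 values an array lay far from the others, where chance gives about 1 in 20, or 3.4. Mos stood at a log2 signal of 8.12 on wild-type replicate 1, against 10.29 to 11.23 on the other wild-type arrays. Knockout replicate 3 was low for 3 genes that fell: Rtl8c at 10.61 against 11.95 to 12.56, Gprasp1 at 9.59 against 11.08 to 11.89, and Wnk4 at 14.25 against 15.09 to 15.32. Knockout replicate 2 was low for Obox1, at 20.36 against 20.91 to 21.21, and for Obox3, at 16.17 against 17.34 to 18.03. Its mean correlation with the other knockout arrays was 0.896, against 0.921 to 0.934 for the others. Psme3 stood at 7.15 on wild-type replicate 6, against 9.79 to 10.87, and the dimmer probe of mCG14666.2 at 8.40 on wild-type replicate 1, against 7.25 to 7.66. The calls of Mos, Rtl8c, Gprasp1 and Wnk4 held with any single array left out. This is little support, since these genes were named for groups that do not overlap.

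Of the 6088 tested probes, 3077 differed between the genotypes. Of 100 splits drawn from the 462 possible ones, 1, the real split, gave as many. The highest other split drawn gave 1055, which argues against a chance division of these arrays. Splits of arrays cannot judge a chance difference between the females or pools behind the groups, since these are not given. A difference in brightness that keeps the order of the probes is argued against by rank correlations, which reached at most 0.790 in 36 pairs of arrays of different genotype and at least 0.821 in 30 pairs of the same genotype. Calls of at least 2-fold made without knockout replicate 2 and wild-type replicate 2, with 7361 and 7102 probes above background, kept their direction between those arrays in 80.4% of probes, 92.2% of the lower and 73.3% of the higher ones. The share of higher ones lay between the bounds set for and against a lower sensitivity of the wild-type arrays, 60% and 75%. But this pair leaned to the wild type, with 38.5% of probes above 0 among those with an adjusted p of 0.5 or more. Its median was -0.23 over all tested probes. The lean works against the share of rises kept and in favour of that of falls. Whether sensitivity had a part thus stays open for the rises, and the 92.2% of the falls may overstate how well they held. Loss of Dicer, and differences in the females or in oocyte maturity, which the labels do not give, stay open and untested. So does a difference in processing between the groups, since the array numbers in the titles run through all knockout arrays before the wild-type arrays.

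The tested gene probes were 2.99-fold brighter on the knockout arrays, a log2 difference of 1.58 (95% confidence interval 0.97 to 2.19). The difference was 1.46 (0.81 to 2.10) for probes above background on all 12 arrays and 0.26 (-0.03 to 0.55) over all probes, most of them at the noise floor. Stronger hybridization, staining or scanning is argued against by the hybridization controls, at 0.073 (-0.29 to 0.43), and a higher yield of in vitro transcription by its controls, at -0.26 (-0.85 to 0.33), since both intervals lie below those of the tested and of the detected probes. Whether more messenger RNA entered the knockout reactions cannot be told apart from more messenger RNA per oocyte, since oocyte numbers are not given. On average 15.8% of the reverse transcription control spots were above background, too few to judge this question or the yield of reverse transcription. Any of these may lie behind the balance of rises and falls.

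Above background on all knockout arrays and on no wild-type array were 178 probes, among them Fgf21, Pdxp and Unkl, against 3 the other way round. Gene probes about 3-fold dimmer on wild-type arrays are argued against as the whole cause: with each knockout and wild-type array left out in turn, probes picked in the same way from the other 10 arrays differed between the left-out arrays by more than their gene probes did, by a median of 1.31 on the log2 scale (0.48 to 2.15 over 36 pairs that share arrays). In the pair of replicates 2 the 409 probes so picked differed by a median of 1.16 (quartiles 0.05 and 2.25), between the bounds of 1 and 2 set beforehand, and 252 were above background on the knockout and 120 on the wild-type array, so lower sensitivity may account for a part of them. RNA of other ovarian cells could not be judged, as 2 of 58 listed markers, Sfrp4 and Hba-a1, were named, each above background on at most 1 knockout array. A role of Dicer stays open and untested.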

How the results depend on the processing

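The alternatives that use control spots, tested probes alone, parts of the array, a shift by the median or a left-out pair were chosen after seeing the data. For the 20 genes named for their rise or fall, whose groups were chosen not to overlap, 521 of 552 values under an alternative kept direction and threshold, 21 kept direction only and 10 changed sign; 9 genes, all rises, kept both wherever they were tested. Leaving out each array in turn kept all 20 calls and gave 1549 to 1826 higher and 1259 to 1387 lower probes. The cause of the following changes was not tested beyond the construction of each alternative. The scanner software's normalized signal gave 511 lower probes, 430 of them at least 2-fold. The deposited table, scaled within each group, gave 3842 higher and 146 lower probes (at least 2-fold, 3491 and 105), with Mapk1ip1 at 0.048, Hsd3b4 at 0.13, Gnl2 at 0.19 and Obox1 at 0.49 (log2). Scaling to in vitro transcription controls gave 4038 and 64 (3872 and 59), with Wwp1 at 0.028, Wnk4 at 0.18, Mapk1ip1 at 0.31, Hsd3b4 at 0.40, Gnl2 at 0.45 and Obox1 at 0.71. Scaling to hybridization controls gave 3460 and 146 (3221 and 112), with Hsd3b4 at 0.032, Gnl2 at 0.085 and Obox1 at 0.35. These 3 settings shift nearly all probes upward, so that the 1508 probes at least 2-fold higher were kept by construction. Of those 1508 and the 1043 at least 2-fold lower, median centring kept 1250 and 1042, cyclic loess 1239 and 1039, and quantile normalization over tested probes 1243 and 1043. In that order they moved the median log2 fold change from 0.18 to -0.19, -0.08 and -0.15, which favours keeping the falls by construction. Testing only the 2979 probes above background on all 12 arrays gave 707 higher and 1206 lower probes (467 and 818 at least 2-fold), or 37.0% higher against 55.6%; a rise from below background cannot enter there. Genes that had not passed the threshold changed sign: Obox1 was at 0.020 with array weights, 0.057 without the closest pair and between -0.12 and 0.055 with each array left out, the highest without knockout replicate 2, and Psme3 at -0.24 with median centring, -0.27 with cyclic loess, -0.23 with quantile normalization over tested probes and between -0.26, without wild-type replicate 6, and 0.50, without knockout replicate 2, with each array left out. The mean within-group minus between-group correlation was 0.139 over tested probes and 0.0595 over all probes, most of which sit at the noise floor. Planned but not run were the settings of set tests (camera, fry), of Dicer1 and of microRNA seed sites, for lack of named members and transcripts. No paired analysis was possible because the replicate numbers follow sample order only. A fold against a group below background is a lower bound on the ratio of these group means that leaves out the spread between arrays. One against a group partly below background is imprecise.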

Other observations

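The genes of the next paragraph were chosen after their values were seen, as were the tests on paired probes and, except for its matching by signal, the test on probe classes.

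Another 14 named genes passed the threshold in limma, 7 higher and 7 lower in knockout oocytes. Higher were Cebpb, a transcription factor of differentiation and metabolism (log2 fold change 2.01 ± 0.55 SE, adjusted p = 0.00817), the transcriptional repressor Zbtb18 (1.95 ± 0.44, 0.00275), the Wnt-inactivating enzyme Notum (1.89 ± 0.41, 0.00197), Rraga, a GTPase of amino acid signalling to mTORC1 (1.99 ± 0.65, 0.0206), the imprinted ubiquitin ligase Ube3a (1.23 ± 0.43, 0.0288), Nupr1l (2.73 ± 0.67, 0.00449) and the chaperone subunit Pfdn5 (0.56 ± 0.20, 0.0291). Lower were Trim59 (-1.56 ± 0.31), Tcp10b (-1.09 ± 0.24), the anchoring proteins of protein kinase A Akap7 (-1.05 ± 0.23) and Akap10 (-0.80 ± 0.22), the nuclear envelope phosphatase Ctdnep1 (-1.02 ± 0.34), the peptidase Dpp9 (-0.96 ± 0.21) and Rnf112 (-0.79 ± 0.26). Scaled to hybridization controls, which shifts nearly all probes upward, 7 of the 7 rises and 0 of the 7 falls passed in the same direction, and Rnf112 was higher there, at 0.64 (adjusted p = 0.0468). Scaled to in vitro transcription controls, the 7 rises passed, 7 of the 7 falls had values above 0, and 4 of them passed as higher: Rnf112 at 0.98 (adjusted p = 0.00949), Akap10 at 0.91 (0.0284), Dpp9 at 0.75 (0.0461) and Tcp10b at 0.73 (0.0342). Centred on array medians, 5 of 7 rises passed, without Cebpb (adjusted p = 0.0576) and Rraga (0.0553), and 7 of 7 falls. With cyclic loess 6 of 7 rises passed, without Rraga (adjusted p = 0.0627), and 7 of 7 falls. Median centring and cyclic loess both lowered the median log2 fold change of the tested probes, which favours falls over rises. The sizes of rises in dim probes were smaller in both settings: Notum stood at 1.06 and 1.11, Nupr1l at 1.94 and 1.96, Cebpb at 1.26 and 1.30, Rraga at 1.40 and 1.35, and Zbtb18 at 1.48 and 1.39. Cebpb, Zbtb18, Notum, Rraga and Nupr1l were above background on 2, 2, 1, 3 and 2 of the 6 wild-type arrays in that order.

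Probes designed on AK accessions were more often lower in knockout oocytes than probes with Celera identifiers. Of 261 tested AK probes, 86 were lower and 56 higher, against 1246 lower and 1622 higher of 5696 (Fisher's exact test on the called probes, odds ratio 0.5003, p = 8.66e-05, over probes, which are not independent replicates). The median log2 fold change of AK probes lay -0.55 from that of the others, and a permutation test that shuffled the classes within eighths of signal gave p = 1e-04, the smallest that 10000 shuffles can give, which argues against signal level as the source. The difference was -0.55 with arrays centred on medians and -0.60 with cyclic loess. Which property of these transcripts goes with it was not tested.

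For 183 gene identifiers with 2 tested probes, the fold changes of both probes correlated across genes at r = 0.507 (Spearman's rho 0.430). The highest of 10000 shuffled pairings gave 0.290, which argues against separate noise of each probe as the sole source of the fold changes. Cross-hybridization cannot be judged in this way, since 2 probes of 1 gene may read the same related transcripts. The shuffles were not matched by signal, which fold changes followed after quantile normalization, so a shared signal level may raise r too. Where both probes were called, 53 of 67 pairs moved the same way (79.1%, against 60.7% by chance from the share of higher calls in these pairs), 42 higher and 11 lower, and 14 moved in opposite ways. A fold change from a single probe may therefore not hold for the whole gene, given r = 0.507.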
